A study of Caenorhabditis elegans with 46 samples.

How the data were processed

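RNA from whole Caenorhabditis elegans worms was measured on 46 Affymetrix arrays, 1 per sample, in 2 sets. The time course set had 22 arrays of the wild-type strain N2, 2 per group: fed worms at 0, 24 and 48 h and worms fasted for 3, 6, 9, 12, 18, 24, 36 and 48 h, starting from adults of day 2. The mutant set had 24 arrays, 3 per group: N2, kgb-1, jun-1 and daf-16 worms, each fed and fasted, as adults of day 4. The labels do not give the fasting time of the mutant set or the lesion of any mutant. Per the labels' protocols, total RNA was prepared with Trizol and biotinylated cRNA was made from 100 ng with the Affymetrix 2-cycle assay, and the time course and the mutant set came from 2 and 3 independent experiments.

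The deposited values are linear intensity values, 1 per probe set and array, made by the authors with PLIER, per the submitters' processing notes, which give neither a version nor a normalization. The smallest deposited value was 16.0003, so an offset of 16 was already in the values when they were deposited. Median intensity per array ran from 60.1 to 84 in the time course and from 60.2 to 85.4 in the mutant set. The number of arrays per group limits the precision of every comparison.

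Of 22625 probe sets, 77 control probe sets were left out and 22548 were tested. The annotation table gave 20766 of them 1 gene symbol and 887 several symbols, and 895 were not listed. Genes were named only from probe sets with 1 symbol, and 20701 of these were found in the reference gene table. A gene with several probe sets was represented, for gene lists and gene counts, by the probe set with the highest mean over all arrays, which gave 17118 genes.

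Values were transformed as log2(intensity + 16). Because the array medians differed by 0.39 in the time course and 0.41 in the mutant set (log2), above the limit of 0.2 set for this, arrays were quantile normalized within each set. Each set was fitted with limma (lmFit, then eBayes with an intensity trend), with 1 coefficient per group, no further covariate and 1 spread shared by the groups. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over the 22548 probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. Fasted worms were compared with fed worms of the same age at 24 and 48 h and with fed worms at 0 h at the other times, where no fed worms of the same age were measured. In the mutant set, fasted worms were compared with fed worms in each genotype, and each mutant's response was compared with that of N2 as an interaction. Fed mutants were also compared with fed N2 worms. The 3 interactions share the 6 N2 arrays, and 100 simulations of unchanged groups gave the overlap that this sharing brings with no effect at all.

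Gene lists (29, from 5 to 312 measured genes) were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with p adjusted over the lists. A fasting-induced and a fasting-reduced set were chosen in the time course (48 h, called, at least 2-fold, 1 probe set per gene) and measured in the mutant set, whose arrays had no part in the choice. The difference of each mutant from N2 was tested with camera on the interaction, and the mean of each set per array was compared between fasted and fed worms with an exact two-sided permutation test, whose smallest possible p is 0.1 for 3 arrays against 3. This test exchanged the arrays freely and did not use replicate pairs.

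Genes were named by a fixed rule. It took called probe sets with 1 gene-class symbol whose arrays did not overlap between the compared groups, ranked by log2 fold change: the 8 highest and 8 lowest for fasting at 48 h and for N2 in the mutant set, the 3 highest and 3 lowest for the other time course comparisons and for fed mutants, and the 5 highest and 5 lowest of each interaction, there without the condition on overlap. It added up to 2 risen and 2 fallen members of each list by adjusted p, every member of the list named SCF core subunits, and kgb-1, jun-1 and daf-16. Comparisons, tests, gene lists, this rule and most alternatives were fixed before the data were examined.

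The labels number the replicates in every group. In the mutant set the deviations of same-numbered arrays from their group means correlated at 0.16 to 0.74 in all comparisons, and 24 of 24 arrays correlated best with an array of their own number, so the numbers were taken to pair these samples. Values from a fit with the replicate number as a block are given beside the mutant set results that they change.

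Alternatives were the values as deposited without quantile scaling, offsets of 1 and 50, the brighter part of the probe sets (a mean above the median), a fit without the intensity trend, a fit of all 46 arrays, the replicate block, each array left out in turn, other rules for the sets and an estimated correlation in camera. An offset of 0 and a fit without the 3 arrays that correlated least with their replicates were added after the values had been seen. Where an alternative changed the time course fit, the fasting-induced and fasting-reduced sets were chosen again, so their members differ. With 100 probe sets shifted by 1 and 100 by 2 (log2) in data simulated for the 22548 probe sets, 89% and 100% were called for fasting at 48 h, with 10 false calls, and 66% and 99% for N2 in the mutant set, with 9 false calls. In a separate simulation camera called 5 of 5 shifted lists and 0 of 15 others in each of these comparisons. Both simulations drew every gene independently and without replicate structure. They therefore say nothing of false calls among lists of correlated genes. R 4.3.3 with limma 3.58.1 was used for the tests, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for the plots.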

Results

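Gene expression was measured in fed and fasted worms in 2 designs: a time course of wild-type N2 worms with 11 groups of 2 arrays, and a mutant set of 4 genotypes, fed and fasted, with 3 arrays in each of 8 groups. The genotypes were N2 and mutants of kgb-1, a kinase of the JNK family, jun-1, an AP-1 transcription factor, and daf-16, the FOXO transcription factor of insulin signalling. The study's title names a JNK and AP-1 module in the lifespan response to intermittent fasting, and the comparisons ask how fasting changes expression and whether the change differs without these genes. Arrays of a group correlated with each other at 0.986 or above in the time course and at 0.93 or above in the mutant set, where daf-16 fasted worms had the lowest value. Of 289 called values of named genes, 124 involve a group with a mean intensity under 100, a bound chosen after the values were seen. Their log2 sizes are approximate, since they depend on the offset. With offsets of 0, 1 and 50 all 124 had the same sign and 118 were called each time.

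Within 3 h without food, acs-2, an acyl-CoA synthetase of fatty acid oxidation, rose by 2.18 ± 0.35 (log2, SE, n = 2 per group) and acox-3, a peroxisomal acyl-CoA oxidase, rose by 2.12 ± 0.20. The yolk protein gene vit-1 fell by 1.71 ± 0.28 and the collagen col-80 fell by 1.84 ± 0.31. Of 32 genes of fatty acid beta-oxidation, 8 rose and 0 fell (10 and 1 adjusted over the list alone, 11 and 1 at an unadjusted p under 0.05 in limma). At 6 h adh-1, an alcohol dehydrogenase, was up by 2.92 ± 0.20 and dct-7 by 3.44 ± 0.30. At 9 h fmo-2, a flavin-containing monooxygenase, had risen by 2.74 ± 0.42. The folate transporter gene folt-2 fell by 4.30 ± 0.33.

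Against fed worms at 0 h the count of called probe sets grew at each time from 3 to 36 h. Against fed worms of the same age it was 7266 at 24 h and 6795 at 48 h, so no widening was seen there. Called probe sets numbered 100 higher and 152 lower at 3 h, 249 and 248 at 6 h, 1443 and 733 at 9 h, 2246 and 1391 at 12 h, 4013 and 4234 at 18 h, 3721 and 3545 at 24 h, 4470 and 4612 at 36 h and 3617 and 3178 at 48 h. Small heat shock genes were among the largest rises from 12 h on, with hsp-12.6 up by about 3.91 at 12 h (3.02 to 4.77 over the offsets) and 5.36 at 36 h (4.40 to 6.24), from a mean intensity of 18.3 in fed worms, at background. The collagen col-80 fell by 3.72 ± 0.31 at 12 h and fell by 5.10 ± 0.31 at 36 h. A list of 27 genes, named SCF core subunits, also holds cul-2, cul-3 and rbx-2, so it is not limited to SCF ubiquitin ligases. The study chose it on these samples, so that its direction is not independent evidence. Of its genes 14 rose and 0 fell at 9 h (14 and 0 adjusted over the list alone, 15 and 2 at an unadjusted p under 0.05 in limma), and 17 rose and 3 fell at 18 h (18 and 4 adjusted over the list alone). Comparisons at 3, 6, 9, 12, 18 and 36 h are with fed worms at 0 h, so that 1 pair of fed arrays enters all 6 and fasting is not separated from age. With the values as deposited a larger share of calls was higher: 1925 higher and 459 lower at 9 h, 3077 and 646 at 12 h, 5059 and 2826 at 18 h, 5491 and 3334 at 36 h and 5027 and 2173 at 48 h. At 18 and 36 h this turned the balance from lower to higher. The median intensity was 60.1 to 66.9 in fed arrays and 81.8 and 84 after 48 h of fasting, so quantile scaling removed a difference that went with fasting. Without 1 of the arrays compared, the count of called probe sets ran from 123 to 169 at 3 h (lowest without fed 0 h replicate 1), and, lowest without fasted replicate 2, from 198 to 325 at 6 h, 968 to 1537 at 9 h, 1682 to 2808 at 12 h and 5066 to 7681 at 18 h.

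**Figure D1:**
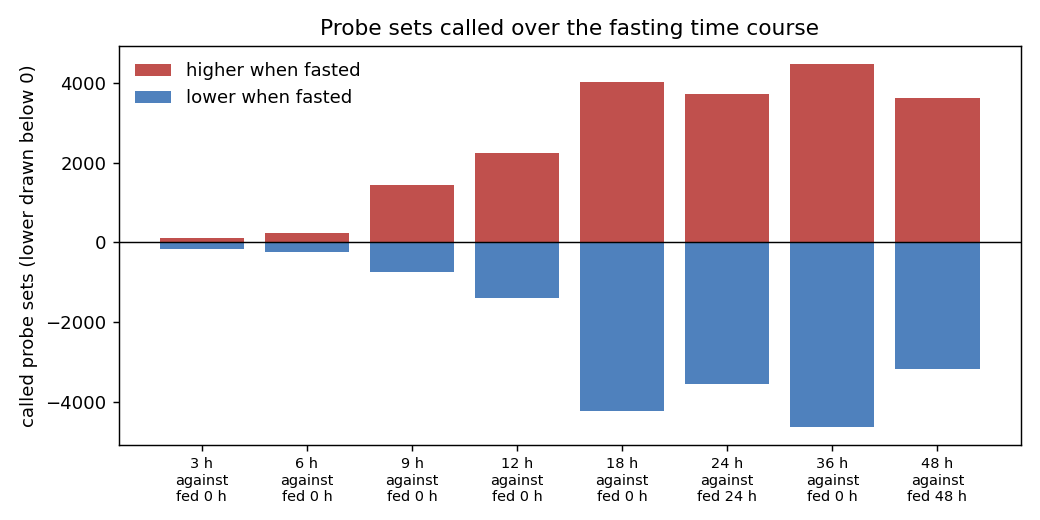
Number of probe sets called higher (red, above 0) and lower (blue, drawn below 0) in fasted than in fed N2 worms at each time of fasting, with the fed group of each comparison named under its bar (n = 2 arrays per group). The count grew from 252 at 3 h to 8247 at 18 h.

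**Figure D2:**
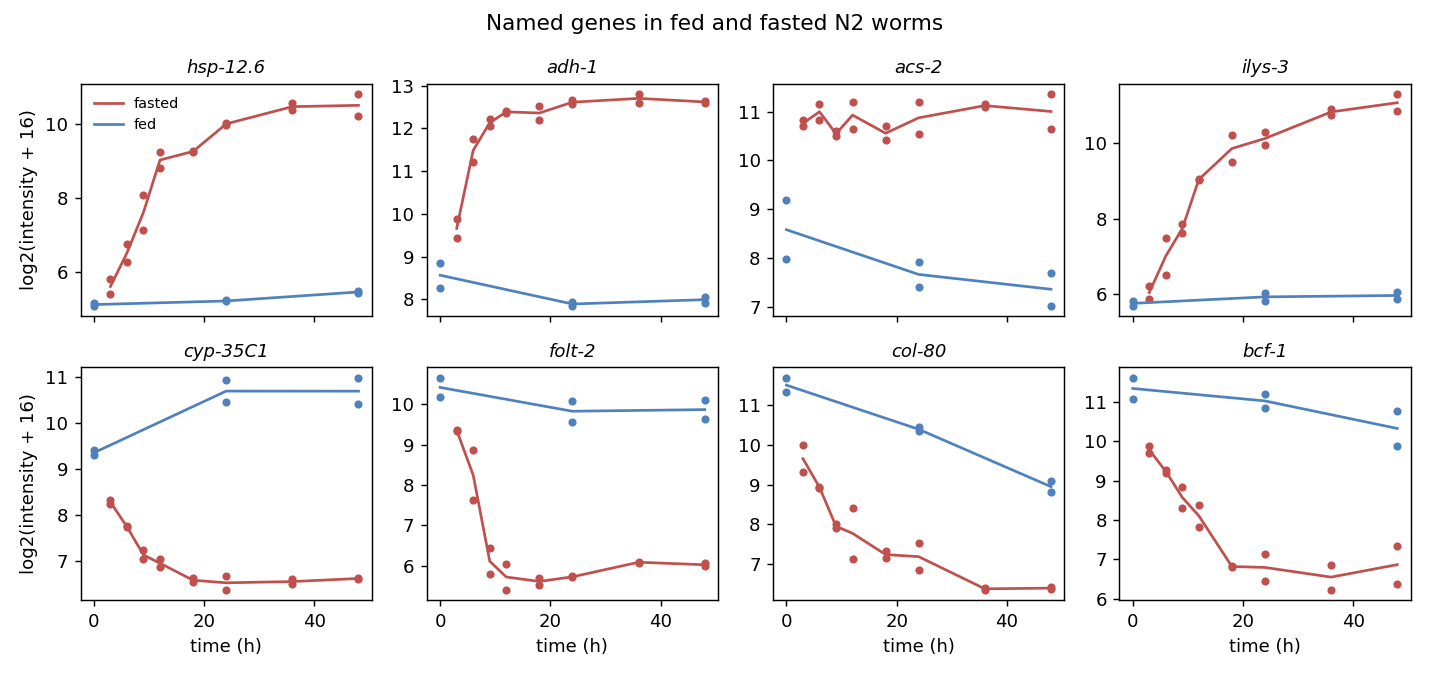
Expression of 8 named genes, as log2(intensity + 16), against hours, in fasted (red) and fed (blue) N2 worms of the time course, with 1 point per array and lines through the means of 2. The upper panels show genes that rose with fasting and the lower panels genes that fell, and against fed worms at 0 h acs-2 was up by 2.18 at 3 h and hsp-12.6 by 3.91 at 12 h and 5.36 at 36 h.

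After 48 h the largest rises against fed worms of the same age were in ilys-3, an invertebrate-type lysozyme, the small heat shock genes hsp-12.6 and hsp-12.3, and adh-1, by 4.62 ± 0.20 (log2, SE, n = 2 per group). The first 3 had 5.09, 5.05 and 5.04, but their fed worms read 45, 27.4 and 35.3, near background. Over the offsets their values ran from 4.48 to 5.50, 4.26 to 5.69 and 4.34 to 5.56, so their order is not settled. The lysozyme ilys-2, spp-27, the water and glycerol channel aqp-1 and the lipid-binding far-7 followed at 4.32, 4.09, 3.86 and 3.78. Among the largest falls, the cytochrome P450 genes cyp-35A3 and cyp-35C1 had -4.87 ± 0.31 and -4.07 ± 0.18. The gene ctsa-1.2 had -4.58 ± 0.16 and the saposin-like spp-4 had -4.23 ± 0.19. Adjusted p from limma ran from 4e-11 for ctsa-1.2 to 2.3e-05 for hrg-11.2 among these 16 genes, which included sysm-1, folt-2 and far-3.

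At 48 h 88 of 146 collagens fell and 1 rose (99 and 1 adjusted over the list alone), among them col-101 at -3.46 and col-183 at -3.12. The adjusted p was 4.62e-20 in camera, and adjusted p = 0.151 with an estimated correlation. Of 39 germline and oocyte markers 25 fell and 0 rose (31 and 1 adjusted over the list alone, 31 and 1 at an unadjusted p under 0.05), with syp-2 down by 1.18 and him-3 by 0.92. The list had adjusted p = 0.26 with an estimated correlation. Of 48 neuron markers 22 rose and 0 fell (24 and 0 adjusted over the list alone, 28 and 1 at an unadjusted p under 0.05), with flp-9 up by 1.40 and ric-19 by 1.24. Their adjusted p was 5.70e-06 in camera and 0.04995 with an estimated correlation. Markers of body muscle (4 risen and 8 fallen of 22), pharynx (3 and 2 of 16), intestine (2 and 6 of 16) and hypodermis (3 and 7 of 19) were not called as lists, and adjusted over the list alone their counts were 5 and 8, 3 and 2, 2 and 7, and 3 and 8. The medians of body muscle and hypodermis markers turned from -0.18 and -0.11 to 0.073 and 0.023 with the values as deposited.

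At 48 h, beside a germline list median of -0.78, 16 of the 27 genes of the SCF list rose and 3 fell (18 and 3 adjusted over the list alone), with skr-14 up by 1.95 ± 0.31, skr-10 by 1.77 ± 0.23 and the cullin cul-6 by 1.03 ± 0.15, and skr-17 down by 0.91 ± 0.12. The list's adjusted p was 0.000729 in camera and adjusted p = 0.168 with an estimated correlation. As the list was chosen on these samples, neither is independent evidence. Of 312 F-box genes, which encode the substrate receptors of SCF ligases, 111 rose and 17 fell (124 and 20 adjusted over the list alone, adjusted p = 0.155 with an estimated correlation). Of 27 autophagy genes 14 rose and 1 fell (17 and 1 adjusted over the list alone), with sqst-1, a cargo receptor, up by 1.80 and atg-16.2 by 1.49. The list had adjusted p = 0.0515 with an estimated correlation. Of 14 JNK and AP-1 pathway genes 9 rose and 0 fell (9 and 0 adjusted over the list alone, 10 and 0 at an unadjusted p under 0.05), with sek-1, a MAP kinase kinase, up by 1.29 and kgb-2 by 1.22. The list had an adjusted p of 0.04995 with an estimated correlation. Of 23 chaperones 8 rose and 2 fell (8 and 2 adjusted over the list alone), with an adjusted p of 0.04995 with an estimated correlation.

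At 48 h 80 of 259 nuclear hormone receptors rose and 9 fell (85 and 10 adjusted over the list alone), with nhr-8 up by 1.71, and the call held with an estimated correlation (adjusted p = 0.0204). Of 32 beta-oxidation genes 6 rose, with acs-2 up by 3.64, and 5 fell, with cpt-5 down by 1.35, and the list was not called (adjusted p = 0.745; 6 and 5 adjusted over the list alone). Of 22 genes of fatty acid synthesis 2 rose and 4 fell (4 and 5 adjusted over the list alone), with fat-7, a stearoyl-CoA desaturase, down by 2.69. Of 107 glutathione and glucuronosyl transferases 17 rose and 37 fell (19 and 40 adjusted over the list alone), with ugt-22 down by 3.61. That list had adjusted p = 0.122 with an estimated correlation. Lysosomal proteases had 2 risen and 10 fallen of 25 (3 and 11 adjusted over the list alone), with asp-14 down by 3.27. They had adjusted p = 0.122 with an estimated correlation. Of the 15 targets of DAF-16 measured, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with mtl-1, a metallothionein, up by 1.54 and lys-7 down by 1.51. They had adjusted p = 0.135 with an estimated correlation.

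Of the 29 lists 16 were called at 48 h, 12 up and 4 down, and 4 held with an estimated correlation: nuclear hormone receptors, JNK and AP-1 pathway genes, chaperones and neuron markers. Insulin-like peptides, lipases, sugar metabolism and mitochondrial respiration, also called up, had adjusted p = 0.122, 0.122, 0.122 and 0.57 with an estimated correlation. Without 1 of the fed 48 h arrays, replicate 1, the count of called probe sets was 4263 in place of 6795.

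In fed worms 263 probe sets were higher and 139 lower at 48 h than at 0 h. The collagen col-183 rose by 3.11 ± 0.16 and cyp-35A4 by 3.08 ± 0.31, (n = 2 per group). The collagen col-80 fell by 2.55 ± 0.31 and col-20 fell by 2.23 ± 0.19. Of 107 glutathione and glucuronosyl transferases 15 rose and 4 fell (21 and 6 adjusted over the list alone). Without any 1 of the 4 arrays the count of 402 was lower, from 137 (without fed 48 h replicate 2) to 246 (without fed 0 h replicate 2).

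In the mutant set the targeted genes were read first. The brighter of the jun-1 probe sets had a mean intensity of 705 ± 99.1 in fed N2 worms and of 19.21 ± 3.85 in fed jun-1 worms (SD, n = 3), at the floor of the deposited values, so that the log2 difference of -4.33 (adjusted p = 6.9e-11, limma) is approximate and ran from -5.14 to -3.44 over the offsets. In fasted worms it stood at 559 ± 67.3 in N2 and 20.46 ± 6.01 in jun-1. The other jun-1 probe set differed by -0.30 (adjusted p = 0.84). The kgb-1 probe set read 173.7 ± 17.7 in fed N2 and 186.7 ± 33.3 in fed kgb-1 worms, and 183.8 ± 34.8 and 212.2 ± 12.5 in fasted ones. Where it lies relative to the lesion is not given, so it checks nothing about this label. The daf-16 probe sets differed in fed daf-16 worms by -0.44 ± 0.09 (adjusted p = 0.028), -0.90 ± 0.23 (adjusted p = 0.13, and 0.013 with the replicate block), -0.43 (adjusted p = 0.64) and -0.35 (adjusted p = 1).

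In fasted N2 worms of the mutant set adh-1 rose by 3.82 ± 0.32 and acs-2 by 3.66 ± 0.35 (log2, SE, n = 3 per group). The C-type lectin gene clec-61 rose by about 4.13 (3.35 to 4.79 over the offsets), from 26.3 in fed worms, near background. The gene clx-1 read 60.2, 107 and 93.1 in the fed and 4257, 19688 and 31213 in the fasted N2 arrays (deposited intensity). Its fitted change of 6.55 is approximate, because the fed arrays lay near background and quantile scaling set the 2 brightest fasted arrays to the same top value, 13.78. In the time course clx-1 exceeded an intensity of 1000 in 4 of the 6 arrays fasted for 24 h or longer, and its replicates at 48 h read 53.99 and 30518. The genes spp-27, ilys-3, far-7 and mtl-1 followed at 3.61, 3.55, 3.46 and 3.31. Among the largest falls, bcf-1 had -4.88 ± 0.43, hrg-11.2 had -4.57 ± 0.30 and sysm-1 had -4.37 ± 0.43. They were followed by clec-265, ctsa-1.2, hrg-11.3, clec-67 and ilys-5 at -3.97, -3.96, -3.77, -3.55 and -3.46. Called probe sets numbered 767 higher and 489 lower, 1671 and 1046 with the replicate block, and 1067 and 404 with the values as deposited. Without N2 fed replicate 2, N2 fed replicate 3 or N2 fasted replicate 3 the count of 1256 for N2 fasted against fed was 639, 631 or 826.

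The genes changed in N2 overlapped those of the time course, whose arrays are other samples. Of 622 genes that rose in N2 here, 528 had risen at 48 h, where independent lists would share 103.9. Of 391 that fell, 291 had fallen, where independent lists would share 57.1. In opposite directions 6 and 7 genes were called. Across genes, which are not independent replicates, the fold changes correlated at 0.71.

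Of the 27 genes of the SCF list 8 rose and 0 fell in N2 (11 and 0 adjusted over the list alone, 13 and 0 at an unadjusted p under 0.05, and 13 and 0 with the replicate block), with skr-14 up by 1.09 and skr-15 by 0.92. This list, chosen by the study on these samples, had an adjusted p of 4.51e-06 in camera, which is not independent evidence. It had adjusted p = 0.0544 with an estimated correlation. Of 15 DAF-16 targets 7 rose and 0 fell (10 and 0 adjusted over the list alone, 10 and 1 at an unadjusted p under 0.05), with hsp-12.6 up by 2.90 and nnt-1 by 2.44 (adjusted p = 0.0544 with an estimated correlation). Of 73 cytochrome P450 genes 13 rose and 3 fell (14 and 4 adjusted over the list alone), with cyp-34A9 up by 3.28. It had adjusted p = 0.0544 with an estimated correlation. Of 32 beta-oxidation genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, 7 and 0 at an unadjusted p under 0.05). It had adjusted p = 0.0544 with an estimated correlation. Of 14 JNK and AP-1 pathway genes 0 passed limma's test (1 risen and 0 fallen adjusted over the list alone, 2 and 0 at an unadjusted p under 0.05, and 1 and 0 with the replicate block), with an adjusted p of 0.565 in camera.

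In the tissue markers of the same worms, 3 of 16 intestine markers fell and 0 rose (8 and 0 adjusted over the list alone, 9 and 0 at an unadjusted p under 0.05, 7 and 0 with the replicate block), with asp-1 at -1.91 and act-5 at -1.5. The list had adjusted p = 0.0793 with an estimated correlation. The germline list had a median of -0.27, beside -0.78 at 48 h of the time course, with 0 members called by limma (0 adjusted over the list alone, 1 higher and 5 lower at an unadjusted p under 0.05, and 5 lower with the replicate block), and adjusted p = 0.479 with an estimated correlation. Collagens had a median of -0.64, with 3 of 146 fallen (2 adjusted over the list alone, 55 with the replicate block), and adjusted p = 0.372 with an estimated correlation. Of the 29 lists 21 were called, 11 up and 10 down, and 0 with an estimated correlation.

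Fasting called fewer probe sets in each mutant than in N2, which by itself does not show that the responses differ. In kgb-1 worms 48 were higher and 178 lower (123 and 321 with the replicate block), in jun-1 worms 185 and 481 (669 and 952), and in daf-16 worms 508 and 547 (1107 and 973). Of the genes of the SCF list 0 were called by limma in kgb-1 worms (6 risen adjusted over the list alone, 8 at an unadjusted p under 0.05, 5 with the replicate block), 6 rose in jun-1 worms (8 adjusted over the list alone) and 7 in daf-16 worms (9 adjusted over the list alone). As a direct test, the SCF list was not called in any interaction, with medians of -0.14 (adjusted p = 0.094), -0.08 (adjusted p = 0.504) and -0.076 (adjusted p = 0.488) for kgb-1, jun-1 and daf-16. The count in kgb-1 was 115, 126, 145 or 140 without fed replicate 2, fed replicate 3, fasted replicate 1 or fasted replicate 3, in jun-1 397 without fed replicate 3 and 408 without fasted replicate 2, and in daf-16 661 without fed replicate 3, or 696 without the 3 arrays that correlated least.

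The fasting-induced set of the time course differed from N2 in its response in each mutant. Its 818 genes had a median change of 0.75 in N2, 0.37 in kgb-1, 0.45 in jun-1 and 0.52 in daf-16 worms, and 96.9%, 94.5%, 89.9% and 90.3% of them were higher in fasted worms. The set's mean per array was 8.49 ± 0.071 in fasted and 7.65 ± 0.10 in fed N2 worms, 8.27 ± 0.079 and 7.87 ± 0.097 in kgb-1, 8.16 ± 0.087 and 7.69 ± 0.036 in jun-1, and 8.21 ± 0.12 and 7.60 ± 0.069 in daf-16 (SD, n = 3). Fasted and fed arrays did not overlap in any genotype, and the exact permutation p of 0.1 is the smallest that 3 unpaired arrays against 3 allow. The permutation ignores the pairing by replicate number, under which fewer arrangements exist and the smallest p would be larger. Against N2 the median difference was -0.40 in kgb-1, -0.32 in jun-1 and -0.22 in daf-16, with adjusted p of 6.02e-39, 4.63e-23 and 1.99e-10 in camera and 0.000134, 0.00116 and 0.0167 with an estimated correlation. Over all alternatives the adjusted p ran from 4.37e-46 to 0.000134 in kgb-1, from 4.6e-27 to 0.00116 in jun-1 and from 4.08e-15 to 0.0167 in daf-16. The replicate block together with an estimated correlation, which lost list calls in the kgb-1 and daf-16 interactions, was not run for either set. Single arrays moved the daf-16 difference, to -0.34 without its fasted replicate 1 and to -0.15 without its fasted replicate 2. Chance was not excluded as the source of the difference in daf-16, nor in jun-1 among the 32 splits of the arrays that part the replicate pairs (2 as large, a share of 0.0625). In jun-1 the split as large beside the real one had the opposite sign (0.326). These 32 also include splits that exchanged unequal numbers of fed and fasted arrays, which brings the genotypes' difference into the interaction. Their shares therefore do not settle whether chance gives the difference. Of the 35 other jun-1 splits that exchanged equal numbers of fed and fasted arrays 0 were as large. In kgb-1 1 of the 30 other splits that exchanged equal numbers of fed and fasted arrays was as large.

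The 544 genes of the fasting-reduced set had medians of -0.71 in N2, -0.41 in kgb-1, -0.60 in jun-1 and -0.55 in daf-16 worms. The set's mean per array (SD, n = 3) was 7.79 ± 0.13 in fasted and 8.81 ± 0.099 in fed N2 worms. In kgb-1 it was 7.62 ± 0.14 and 8.39 ± 0.27. In jun-1 it was 7.50 ± 0.12 and 8.50 ± 0.17, and in daf-16 7.68 ± 0.27 and 8.63 ± 0.084. By these means each mutant lay below N2 in both states, so a smaller fall goes with a lower fed level, not a higher fasted one. With the values as deposited the set was chosen again (389 genes), so that members and scaling both changed, and the medians were -0.97, -0.80, -1.06 and -0.92. The set was also chosen again without single 48 h arrays. Without fasted 48 h replicate 1 the medians were -0.25 in kgb-1, -0.21 in jun-1 and -0.36 in daf-16. In jun-1 the median was -0.29 without fed 48 h replicate 2 and -0.92 without fasted 48 h replicate 2. The difference from N2 was 0.26 in kgb-1 (adjusted p = 2.99e-12, and 0.00971 with an estimated correlation). Chance was not excluded for the set's difference in any mutant (20, 29 and 19 of 100 splits as large in kgb-1, jun-1 and daf-16). The difference was 0.17 in jun-1 and 0.12 in daf-16 (adjusted p = 0.0224 and 0.0236). Both calls were lost with an estimated correlation (adjusted p = 0.312 for each) and in the set chosen again from the values as deposited (0.01 and 0.02). Over all alternatives the adjusted p ran from 1.03e-05 to 0.754 in jun-1 and from 0.000765 to 0.715 in daf-16. Both calls were also lost without single arrays: for both mutants without fed 48 h replicate 1, fasted 48 h replicate 2, N2 fed replicate 2 or N2 fasted replicate 1, in jun-1 also without its fed replicate 1 or fasted replicate 3, and in daf-16 without its fed replicate 1 or fasted replicate 2, with medians from 0.04 to 0.16 in jun-1 and from 0.10 to 0.13 in daf-16.

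**Figure D3:**
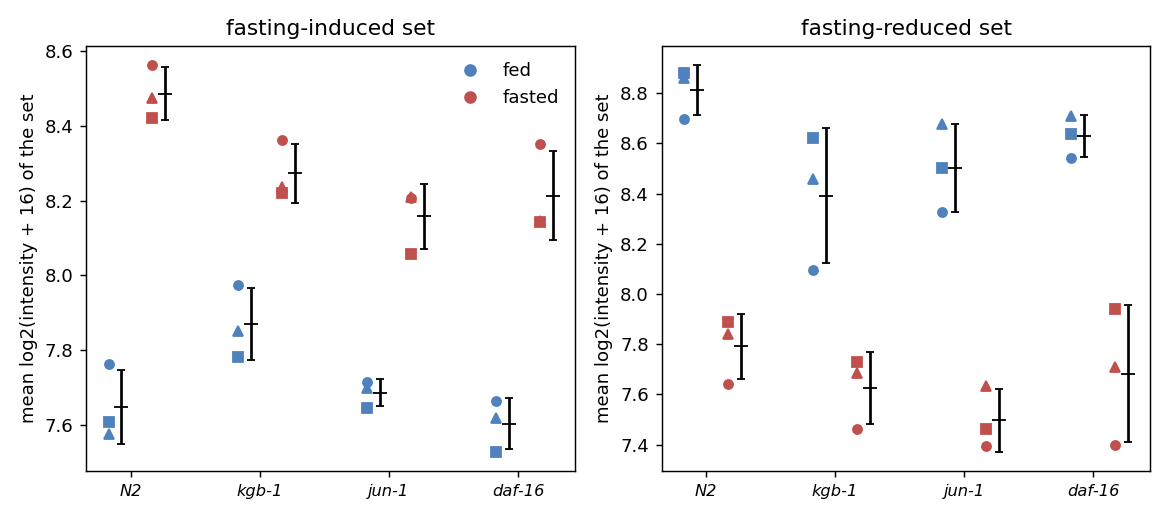
Mean of the fasting-induced set (left, 818 genes) and the fasting-reduced set (right, 544 genes), as log2(intensity + 16), in each array of the mutant set, by genotype, in fed (blue) and fasted (red) worms. Circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of 3 arrays. In N2 the induced set went from 7.65 to 8.49 and in kgb-1 from 7.87 to 8.27.

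Against N2, 1 probe set was higher and 6 lower in the kgb-1 interaction. The gene clx-1 had a log2 fold change of -0.03 in kgb-1 worms, an approximate difference of -6.58 (adjusted p = 4e-07), and clec-61 had 1.32 in kgb-1 and 4.13 in N2 (difference -2.81, adjusted p = 0.035, a call lost with offsets of 0 and 1). The gene adh-1 had 1.1 and 3.82 (difference -2.72 ± 0.45, adjusted p = 0.024), from a level 2.31 ± 0.32 higher in fed kgb-1 than in fed N2 worms. With the replicate block 7 probe sets were higher and 15 lower, and 618 had an unadjusted p under 0.05 without it. Outside the naming rule, and chosen after their values were seen, were acs-2, whose other probe set differed by -2.87 while its representative was not called, and Y6E2A.4, with 2 probe sets at -2.09 and -1.15. The 1 higher probe set lists several genes and is not named. The splits of the arrays did not settle whether chance gives this count of 7. Of 100 splits 11 gave as many, but each of the others among these exchanged unequal numbers of fed and fasted arrays, which brings the genotypes' difference into the interaction. The 30 with equal numbers called 0 in limma and up to 3898 at an unadjusted p under 0.05. The count ran from 1 (without N2 fed replicate 2, among others) to 13 (without N2 fed replicate 1) and moved without 11 of the 12 arrays.

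By list, the 15 DAF-16 targets differed from N2 by a median of -1 in kgb-1 worms (adjusted p = 1.04e-10 in camera, and 0.0333 with an estimated correlation), beta-oxidation genes by -0.14 (adjusted p = 0.0147, and 0.0447) and cytochrome P450 genes by -0.11 (adjusted p = 0.00502, and 0.0333). Single members passed limma's test in none of these 3 lists (6, 1 and 3 lower adjusted over the list alone, and 7, 4 and 7 lower with 0, 0 and 2 higher at an unadjusted p under 0.05). With the replicate block the 3 lists had adjusted p = 0.112, 0.149 and 0.112 with an estimated correlation. In all 11 of 29 lists were called in this interaction, of which 3 held with an estimated correlation, and chance was not excluded for the count of lists (46 of 100 splits gave as many).

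In jun-1 worms 36 probe sets were lower and 4 higher in the interaction (89 and 16 with the replicate block, and 1005 at an unadjusted p under 0.05). The genes clx-1 and clec-61 had log2 fold changes of -0.53 and -0.25 there and differences from N2 of -7.09 (approximate, adjusted p = 9.9e-08) and -4.38 (adjusted p = 0.00012). The aspartyl protease asp-17 fell by 4.53 in jun-1 beside -0.68 in N2 (difference -3.85 ± 0.52). The gene clec-60 fell by 2.78 beside 0.37 in N2 (difference -3.15 ± 0.41), from a level 2.91 higher in fed jun-1 than in fed N2 worms. Most of its difference thus lies in the fed worms. The P450 gene cyp-34A9 had 0.10 in jun-1 and 3.28 in N2 (difference -3.19 ± 0.56). Smaller differences were called for thn-1 (-2.29), lipl-4, a lysosomal lipase (-1.64), spp-14 (-1.79), the nuclear hormone receptor nhr-68 (-1.36), fbxa-6 (-0.99) and cyp-34A10 (-0.80), of which lipl-4 and fbxa-6 lost their calls with offsets of 0 and 1. The higher calls, named after their values were seen, were Y60C6A.1 at 1.93, C17H12.6 at 2.33, C05D12.3 at 2.34 and 1 probe set with several genes. The splits did not settle chance for this count of 40 either: 12 of 100 gave as many, the others all with unequal numbers exchanged, and the 35 with equal numbers called 0 in limma and up to 4525 at an unadjusted p under 0.05. The count was 77 without N2 fasted replicate 1, from 16 to 21 without N2 fed replicate 2 or 3, N2 fasted replicate 2 or 3, jun-1 fed replicate 3 or jun-1 fasted replicate 2, and 15 without the 3 arrays that correlated least.

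In jun-1 worms DAF-16 targets differed from N2 by a median of -1.5 (adjusted p = 1.19e-13 in camera, and 0.00815 with an estimated correlation), beta-oxidation genes by -0.27 (adjusted p = 9.01e-06, and 0.00093) and P450 genes by -0.12 (adjusted p = 4.68e-06, and 0.00093). In these lists 0, 0 and 2 members were lower by limma's test (9, 4 and 3 adjusted over the list alone, 9, 7 and 15 at an unadjusted p under 0.05, and 1, 3 and 3 with the replicate block). In all 14 of 29 lists were called, of which these 3 held with an estimated correlation, and chance was not excluded for that count (28 of 100 splits).

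In daf-16 worms 23 probe sets were lower and 2 higher in the interaction (46 and 10 with the replicate block, and 919 at an unadjusted p under 0.05). The genes clx-1 and clec-61 had log2 fold changes of -0.15 and 0.16 (differences of -6.70, again approximate, and -3.97), and spp-27 had 0.12 beside 3.61 in N2 (-3.49 ± 0.58). The small heat shock genes hsp-12.6 and hsp-12.3 had 0.35 and 0.22 in daf-16 worms and 2.90 and 3.16 in N2 (differences of -2.55 ± 0.47 and -2.94 ± 0.54). The thaumatin-like thn-1 differed by -3.10, asp-17 by -3.37, lys-7 by -2.56, lipl-4 by -2.07, ugt-1 by -1.67, fbxa-6 by -0.98 and cyp-34A10 by -0.80, the last 2 not called with offsets of 0 and 1. The higher calls, named after their values were seen, were C17H12.6 at 1.82 and Y39B6A.1 at 2.01. Nor did they for this count of 25, where 13 of 100 gave as many, the others all with unequal numbers exchanged, and the 39 with equal numbers called 0 in limma and up to 2407 at an unadjusted p under 0.05. The count was 47 without daf-16 fed replicate 1, from 9 to 16 without N2 fed replicate 2 or 3, N2 fasted replicate 2 or 3, daf-16 fed replicate 2 or 3 or daf-16 fasted replicate 2 or 3, and 11 without the 3 arrays that correlated least.

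The targets of DAF-16, taken as a list, differed from N2 by a median of -1.1 in daf-16 worms (adjusted p = 2.35e-05), with 2 of 15 members lower (6 adjusted over the list alone). That call was lost with an estimated correlation (adjusted p = 0.198). The P450 list differed by -0.085 (adjusted p = 0.00158, and 0.0291 with an estimated correlation), with 1 of 73 members lower (3 adjusted over the list alone, 2 with the replicate block). With the replicate block the P450 list had adjusted p = 0.117 with an estimated correlation. In all 7 of 29 lists were called, of which 1 held with an estimated correlation, and chance was not excluded for that count (72 of 100 splits). The count was 13 without daf-16 fasted replicate 2 and 12 without the 3 arrays that correlated least.

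**Figure D4:**
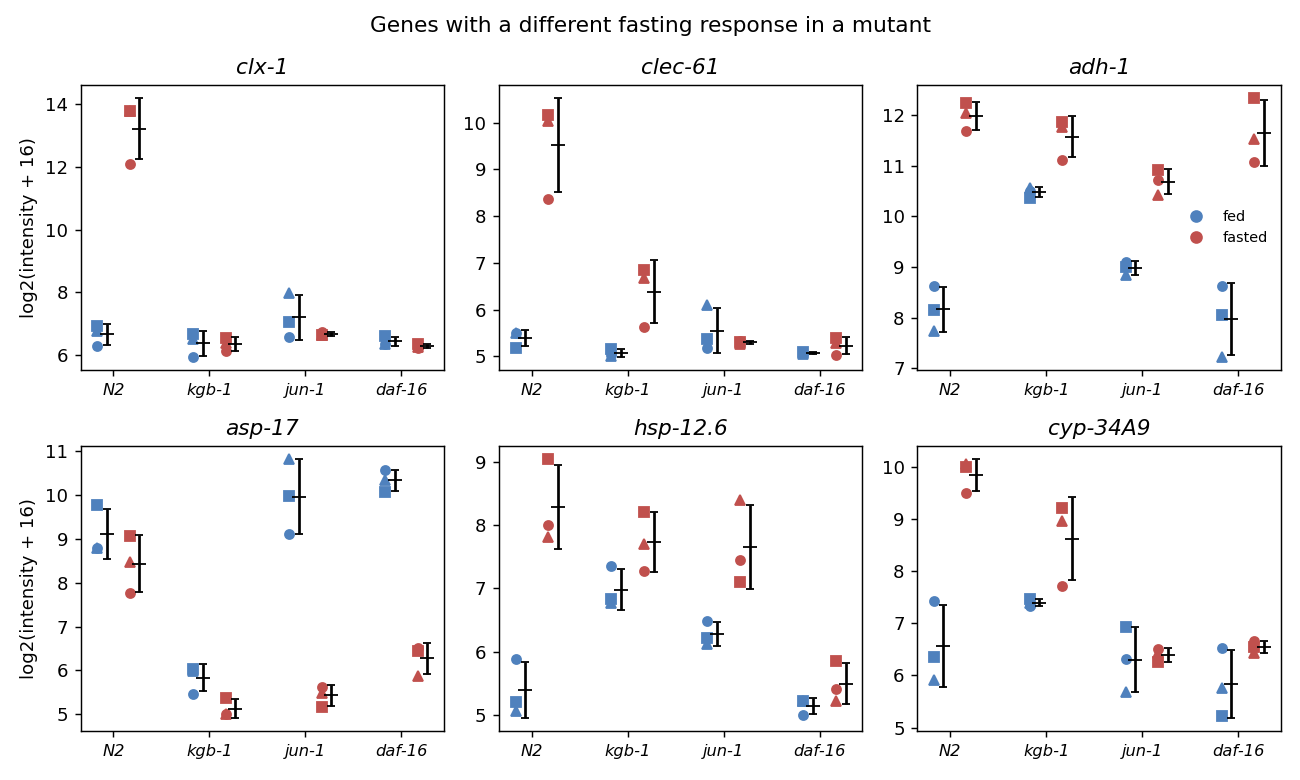
Expression of 6 genes, as log2(intensity + 16), in each array of the mutant set, by genotype, in fed (blue) and fasted (red) worms. Circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of 3 arrays. The clx-1 panel shows a mean of 13.22 in fasted N2 worms, where 2 arrays share the top value of 13.78, and of 6.66 in fed ones.

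The 3 interactions shared calls. Lower calls were shared by 4 probe sets between kgb-1 and jun-1, 4 between kgb-1 and daf-16 and 13 between jun-1 and daf-16, and 4 probe sets were called in all 3. These were clx-1, clec-61, 1 of Y6E2A.4 and 1 that lists several genes, which was higher in kgb-1 and lower in jun-1 and daf-16. Unchanged mutants simulated against the shared N2 arrays gave 0, but had 0.06, 0.11 and 0.02 calls on average in the 3 interactions and so next to none to share. Independent lists, which leave out the shared N2 arrays, would share 0.0096, 0.0061 and 0.037. Neither value tests the overlap, and with 3 N2 arrays per feeding state the controls cannot be split, so that part of it may come from the shared controls. Across genes, which are not independent replicates, the interactions correlated at 0.52, 0.46 and 0.51, where simulated unchanged mutants gave 0.5. Their covariances were 0.047, 0.038 and 0.05 beside 0.054 in the simulation. The simulated value lay above all 3 and may overstate what the shared N2 arrays bring. It therefore cannot show whether there is covariance beyond theirs.

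Fed mutants already differed from fed N2 worms. In kgb-1 worms clec-9 was higher by 4.76 ± 0.84, metl-6 by 2.58 ± 0.19 and adh-1 by 2.31 ± 0.32, and asp-17 was lower by -3.28 ± 0.36, far-3 by -2.79 ± 0.49 and clec-174 by -2.69 ± 0.53 (log2, SE, n = 3 per group). The fasting-induced set was higher by 0.22 in fed kgb-1 worms and the fasting-reduced set differed by -0.42, each with the smallest exact permutation p of 0.1. The permutations in this paragraph did not use the replicate pairs. The reduced set differed by -0.31 in fed jun-1 (exact permutation p 0.1) and by -0.18 in fed daf-16 worms (exact permutation p 0.2), and the induced set by 0.038 and -0.045 (exact permutation p 0.6 and 0.7). Called probe sets numbered 100 higher and 329 lower (488 and 854 with the replicate block). Without kgb-1 fed replicate 1, kgb-1 fed replicate 3, N2 fed replicate 2 or N2 fed replicate 3 the count of 429 was 179, 214, 185 or 189.

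In fed jun-1 worms clec-5 was higher by 3.77 ± 0.44, srlf-34 by 3.31 ± 0.54 and clec-60 by 2.91 ± 0.29, and clec-222 and clec-174 were lower by -3.64 ± 0.44 and -3.46 ± 0.53. Of 220 C-type lectins 7 were higher and 17 lower (8 and 31 adjusted over the list alone). In fed daf-16 worms metl-6 was higher by 2.31 ± 0.19 and dod-23 by 1.15 ± 0.23, and pud-4, pud-3 and mtl-1 were lower by -4.01 ± 0.60, -3.14 ± 0.45 and -2.88 ± 0.43. Of 15 DAF-16 targets 2 were lower (12 adjusted over the list alone, 7 with the replicate block). Calls numbered 79 higher and 227 lower in jun-1 (173 and 462 with the replicate block, 53 and 376 with the values as deposited) and 6 and 92 in daf-16 (16 and 173 with the replicate block). Without N2 fed replicate 3 the counts of 306 and 98 were 162 and 55. The jun-1 count was also 185 without N2 fed replicate 2 and 177 without jun-1 fed replicate 2, and the daf-16 count was 202 without daf-16 fed replicate 1 and 60 without daf-16 fed replicate 2.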

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

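The drawn splits of the arrays, the tests of the interactions and their alternatives were planned. The grouping of the splits by exchanged arrays, the full set of 32 splits and the tests in the last 3 paragraphs were chosen only after the result was seen. The values listed are differences of a mutant's fasting response from that of N2 that passed a test of the difference itself, as log2 fold changes or list medians.

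In kgb-1 worms 7 probe sets differed, among them clx-1 by -6.58, clec-61 by -2.81 (not called with offsets of 0 and 1) and adh-1 by -2.72. The log2 sizes of clx-1, clec-61 and other genes with a group near background are approximate here and below. The fasting-induced set differed by -0.399 and the fasting-reduced set by 0.263. Of 11 lists that differed, DAF-16 targets (-1), beta-oxidation (-0.14) and cytochrome P450 (-0.11) held without the replicate block but not under it, each time with an estimated correlation. The others were lost with it: lipases -0.49 (adjusted p = 0.212 with an estimated correlation), autophagy -0.16 (0.466), mitochondrial respiration -0.1 (0.466), transferases -0.031 (0.586), nuclear hormone receptors -0.059 (0.228), collagens 0.15 (0.897), germline 0.14 (0.643) and pharynx 0.21 (0.611).

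In jun-1 worms 40 probe sets differed, among them clx-1 by -7.09, clec-61 by -4.38, asp-17 by -3.85, cyp-34A9 by -3.19, clec-60 by -3.15 and thn-1 by -2.29. Others were spp-14 by -1.79, lipl-4 by -1.64, nhr-68 by -1.36, fbxa-6 by -0.99 and cyp-34A10 by -0.80, with lipl-4 and fbxa-6 not called with offsets of 0 and 1. The induced set differed by -0.315 and the reduced set by 0.167, a call that was lost with an estimated correlation (adjusted p = 0.312) and with the values as deposited (adjusted p = 0.754, over all alternatives from 1.03e-05 to 0.754). Of 14 lists, DAF-16 targets (-1.5), beta-oxidation (-0.27) and P450 (-0.12) held with an estimated correlation. The others were lost with it: lipases -0.26 (adjusted p = 0.0896 with an estimated correlation), fatty acid synthesis -0.32 (0.0896), sugar metabolism -0.15 (0.0896), lysosomal proteases -0.45 (0.0918), chaperones -0.072 (0.282), lysozymes and antimicrobial peptides -0.23 (0.0918), C-type lectins -0.013 (0.691; 0.024 with the values as deposited, the opposite sign), collagens -0.12 (0.82), vitellogenins -0.21 (0.282), germline 0.29 (0.435) and intestine -0.22 (0.22).

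In daf-16 worms 25 probe sets differed, among them clx-1 by -6.70, clec-61 by -3.97, spp-27 by -3.49, asp-17 by -3.37, thn-1 by -3.10, hsp-12.3 by -2.94, lys-7 by -2.56 and hsp-12.6 by -2.55. Others were lipl-4 by -2.07, ugt-1 by -1.67, fbxa-6 by -0.98 and cyp-34A10 by -0.80, the last 2 not called with offsets of 0 and 1. The induced set differed by -0.216 and the reduced set by 0.12, a call that was lost with an estimated correlation (adjusted p = 0.312) and with the values as deposited (adjusted p = 0.715, over all alternatives from 0.000765 to 0.715). Of 7 lists, P450 (-0.085) held without the replicate block but not under it, each time with an estimated correlation. The others were lost with it: DAF-16 targets -1.1 (adjusted p = 0.198 with an estimated correlation), fatty acid synthesis -0.15 (0.219), sugar metabolism -0.17 (0.219), chaperones -0.17 (0.194), germline 0.19 (0.785) and body muscle -0.31 (0.785).

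For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as large a count: 1256 called probe sets in fasted against fed N2 worms (highest other 0) with 21 lists (12), 226 in kgb-1 (0), 666 in jun-1 (1) and 1055 in daf-16 worms (978), and 429, 306 and 98 for fed kgb-1, jun-1 and daf-16 against fed N2 worms (0, 0 and 8). The daf-16 split with 978 set fasted replicates 1 and 3 and fed replicate 1 against the other arrays. It does not part the replicate pairs as the real split does, and among the 4 splits that part the pairs the highest other count was 0.

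For each interaction 100 splits of the genotype labels were drawn. Over these, the induced set fell under a share of 0.05 in kgb-1 (-0.399, 4 of 100 as large, largest other -0.47) and jun-1 (-0.315, 4 of 100, -0.375). Both counts include the real split. The draw also mixes in splits that exchanged unequal numbers of fed and fasted arrays, so these shares do not exclude chance. Chance was not excluded in daf-16 either (-0.216, 22 of 100, -0.373). It was not excluded for the reduced set in kgb-1 (0.263, 20 of 100, 0.426), jun-1 (0.167, 29 of 100, 0.441) or daf-16 (0.12, 19 of 100, 0.26). Nor was it for the lists (kgb-1 11, 46 of 100, 18; jun-1 14, 28 of 100, 19; daf-16 7, 72 of 100, 20). For the called probe sets (kgb-1 7, 11 of 100, highest other 289; jun-1 40, 12 of 100, 2258; daf-16 25, 13 of 100, 1250) the splits do not settle it. Counts several times the real one point to a structure of the samples. The splits that exchanged equally many arrays among fed and fasted worms called 0 probe sets by limma in all 3 interactions (30, 35 and 39 splits), although at an unadjusted p under 0.05 they reached 3898, 4525 and 2407 beside the real 618, 1005 and 919. Each other split with as many calls as the real one exchanged unequal numbers, which brings the genotypes' difference into the interaction. Of the splits with equal numbers, 12, 3 and 24 called as many lists, 1, 0 and 5 were as large for the induced set and 5, 3 and 8 for the reduced set. Why single splits gave the highest counts was not tested. Among the 14, 20 and 17 drawn splits that part the pairs, the highest other counts were 121, 1415 and 571, and the largest other differences of the induced set were -0.313, 0.326 and 0.262. All 32 such splits were then run for the sets. They too include splits that exchanged unequal numbers of fed and fasted arrays, so their shares do not settle chance. For the induced set 1 was as large in kgb-1, the real split itself, and its share of 0.0312 is the smallest that 32 splits allow. That share is under 0.05, but 1 of the 30 with equal numbers exchanged reached -0.412. In jun-1 2 were as large (0.0625), the other at 0.326 with the opposite sign. In daf-16 3 were (0.0938), and chance was not excluded in these 2 mutants. For the reduced set 7, 11 and 5 were as large.

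The clx-1 signal was high in some arrays and near background in others: over an intensity of 1000 were 3 fasted N2 arrays of the mutant set and 4 time course arrays, the latter all among the 6 fasted for 24 h or longer, and the 2 arrays at 48 h read 53.99 and 30518. An artefact of single arrays unrelated to fasting is argued against, since clx-1 was named from the mutant set and, in the time course, whose arrays are other samples but also named it, the mean of 36 h exceeded that of random arrays (exact one-sided permutation p 0.00246). At 24, 36 and 48 h replicate 2 read 7298.9, 34129 and 30518, and replicate 1 read 45.9, 6066.2 and 53.99. The permutation ignored the replicate number, so it does not separate late fasting from something tied to replicate 2 at these times. The bound was chosen after the values were seen, but no array read between 173 and 4257, and an artefact tied to fasted samples was not tested. A strain difference at the clx-1 locus in the mutants stays open, because fed N2 worms lay at the background of fed mutants (86.8 ± 24 and 86 ± 38.1, SD, a difference of -0.744), so their level shows nothing of the mutants' gene. An effect of the mutated genes on clx-1 is a hypothesis that stays open beside it.

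The induced set had smaller median changes in the mutants. With the values as deposited the set was chosen again (1165 genes), so members and scaling both changed. Its differences from N2 were -0.433 in kgb-1, -0.305 in jun-1 and -0.303 in daf-16. These sizes argue against quantile scaling as the source, for the set chosen again. The largest of the 3 adjusted p was 4.08e-15, in camera at the preset correlation, and does not exclude chance. A higher level in fed worms could apply only to kgb-1, where the fed set lay 0.22 above N2. As the whole cause it is argued against there, since fasted arrays differed from fasted N2 arrays by -0.21 (SD 0.11), but it may account for part. In jun-1 and daf-16 the fed set differed by only 0.038 and -0.045, so the test decides nothing there. Their fasted arrays differed by -0.33 and -0.27 (SD 0.11 and 0.14). A weaker fasting response in all genes stays open: the share of the N2 response kept by the reduced set exceeded that of the induced set by 0.42 ± 0.14 (SD) in jun-1, but in medians by 0.083 ± 0.12 with sets from 24 h and by -0.33 ± 0.093 without the fold minimum, and by 0.27 ± 0.14 in kgb-1 (in medians 0.14 ± 0.16) and 0.19 ± 0.22 in daf-16. A need for these genes in the fasting response remains a hypothesis, with chance not excluded in daf-16, nor in jun-1 among the splits that part the pairs or in kgb-1 among those with equal numbers exchanged. In jun-1 0 of the 35 with equal numbers exchanged were as large. In kgb-1 the largest other split that parts the pairs was -0.313, smaller than the real one.

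After 48 h of fasting germline markers were lower, a call lost with an estimated correlation (adjusted p = 0.26), and neuron markers higher (adjusted p = 0.04995 with it). A smaller share of germline RNA as the whole cause would raise all somatic markers alike. The neuron median lay 0.61 above that of body muscle (0.60 and 0.64 with arrays paired by replicate number). What that number marks in the time course is not given. The permutation over genes (p 0.00017) treats genes on the same arrays as independent, so it does not measure variation between worms. The body muscle median also changed sign with the values as deposited. Only the size of the difference thus speaks against this cause. Quantile scaling is argued against, since with the values as deposited the neuron median lay 0.54 above and the germline median -0.76 from that of all probe sets. A loss of germline beside other changes, and a biological rise of neuron transcripts, may both contribute and stay open.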

How the results depend on the processing

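All alternatives were planned except the offset of 0 and the fit without the 3 least correlated arrays, which were chosen after seeing the data. Where no construction is named the cause was not tested. The balance of higher and lower calls turned under at least 1 alternative at 3, 6, 18, 24, 36 and 48 h and in daf-16 worms. Array signal near the offset limits dim probe sets. With the values as deposited the fasting-reduced set was chosen again (389 genes). It had -0.97 in N2, -0.80 in kgb-1, -1.06 in jun-1 and -0.92 in daf-16, and interactions of 0.01 in jun-1 and 0.02 in daf-16 (adjusted p 0.754 and 0.715, over all alternatives from 1.03e-05 to 0.754 and from 0.000765 to 0.715). An offset of 50, with the set chosen again (365 genes), gave -0.94 in N2, -0.99 in jun-1 and -0.84 in daf-16. The kgb-1 interaction called 4 with an offset of 1, 1 with an offset of 0 and 1 without the intensity trend. In the brighter probe sets, of which fewer were tested, the kgb-1 and daf-16 interactions called 3 and 11, fed jun-1 and daf-16 worms 164 and 38, and the lists 9 at 48 h and 7 in the kgb-1 interaction.

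With all 46 arrays in 1 fit, which shares 1 spread, 79, 167, 738, 1214, 4983, 3984, 5845 and 3659 were called from 3 to 48 h of fasting and 79 in fed worms at 48 h. Fasting called 2132 in N2, 399 in kgb-1, 1289 in jun-1 and 1732 in daf-16, the interactions 33, 106 and 63, and the fed mutants 929, 612 and 218, and the reduced set in jun-1 was -0.37. Without the 3 least correlated arrays fasting in daf-16 called 696, the interactions 13, 15 and 11, fed daf-16 worms 61 and the daf-16 interaction 12 lists, with the reduced set at 0.09 (adjusted p 0.658). With an estimated correlation the lists called were 4 at 48 h, 0 in N2 (limma's camera) and 3, 3 and 1 in the interactions, and the reduced set's 0.17 in jun-1 and 0.12 in daf-16 lost their calls. Sets from 24 h gave the reduced set -0.37 in jun-1. Sets without the fold minimum gave the induced set 0.39, 0.20, 0.25 and 0.26 in N2, kgb-1, jun-1 and daf-16, and the reduced set -0.24, -0.05 and -0.12 in N2, jun-1 and daf-16.

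With the replicate block, which pairs the mutant set, fasting called 2717 in N2, 444 in kgb-1, 1621 in jun-1 and 2080 in daf-16, the interactions 22, 105 and 56, and the fed mutants 1342, 635 and 189. The time course was left unpaired, since its labels do not say what a replicate number marks and each comparison has 2 pairs. Same-numbered deviations correlated there at 0.29 to 0.62, and 22 of 22 arrays correlated best with an array of their own number. With 2 arrays per group the deviations mirror each other, so this count adds little to the correlations. In the time course the block called 541, 961, 3857 and 6188 at 3, 6, 9 and 12 h and 1019 in fed worms at 48 h. The block moved no other count of called probe sets, or of lists called at the preset correlation, by over 1.5 times. With an estimated correlation it lost the calls of DAF-16 targets, beta-oxidation and P450 genes in the kgb-1 interaction and of P450 genes in the daf-16 interaction. It changed calls of 9 of 465 named gene values, all towards a call.

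Without 1 array, which in the time course leaves a lone sample assumed to vary like the other groups, counts ran from 123 to 169 at 3 h, 198 to 325 at 6 h, 968 to 1537 at 9 h, 1682 to 2808 at 12 h, 5066 to 7681 at 18 h, 4944 to 5644 at 24 h, 6677 to 7394 at 36 h, 4263 to 5310 at 48 h and 137 to 246 in fed worms at 48 h. They ran from 631 to 1419 in N2, 115 to 266 in kgb-1, 397 to 734 in jun-1 and 661 to 1249 in daf-16, in the interactions from 1 to 13, 16 to 77 and 9 to 47, and in fed mutants from 179 to 526, 162 to 292 and 55 to 202. Lists ran from 14 to 17 at 48 h, 16 to 21 in N2, and 7 to 15, 12 to 18 and 6 to 13 in the interactions. The induced set ran from 0.68 to 0.82 in N2, 0.29 to 0.44 in kgb-1, 0.40 to 0.49 in jun-1 and 0.39 to 0.58 in daf-16, with interactions from -0.48 to -0.33, -0.38 to -0.26 and -0.34 to -0.15. The reduced set ran from -0.88 to -0.54, -0.59 to -0.25, -0.92 to -0.21 and -0.81 to -0.36, with interactions from 0.20 to 0.34, 0.04 to 0.23 and 0.10 to 0.23.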
